A study of Homo sapiens with 12 samples.

How the data were processed

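RNA from Ishikawa cells, a human endometrial adenocarcinoma line, was hybridised to 12 expression arrays. The labels give 4 groups of 3 arrays: control or shMOF cells, each in a condition called ERα(-) or ERα(+). Total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. What separates ERα(-) from ERα(+), the sequence of the short hairpin and the origin of the replicates are not given in the sources used here. The p-values therefore measure the spread between these arrays, which may be technical.

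The deposited values are on the log2 scale and were made by the authors with Affymetrix Expression Console 1.4.1 and RMA, per the submitters' processing notes. RMA corrects the background, makes the distribution of values equal between arrays and summarises the probes of a probe set. It can compress differences of dim transcripts. The genome build and the annotation behind the probe sets are not given in the sources used here. Each array held 53617 probe sets with 0 missing values. The platform annotation used here gave 1 gene symbol to 16098 probe sets and several to 0, and 37519 probe sets stayed unnamed here. Of the genes, 779 had more than 1 probe set, and the probe set with the highest mean over the 12 arrays stood for each gene. This left 14884 genes, all of which were tested, with no filter on dim genes. Array medians over all probe sets lay between 4.53 and 4.59 on the log2 scale. The number of arrays, 3 in each group, limits the precision.

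A mean was fitted for each of the 4 groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 8 residual degrees of freedom and 5.60 prior degrees of freedom). The comparisons were shMOF against control in ERα(-), shMOF against control in ERα(+), ERα(+) against ERα(-) in control arrays, ERα(+) against ERα(-) in shMOF arrays, and the interaction, which is the shMOF difference in ERα(+) minus that in ERα(-). P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p below 0.05. The 95% interval of a log2 fold change reached a median of 0.33 to either side in the comparisons of 2 groups and 0.46 in the interaction. An exact test of 3 arrays against 3 cannot go below a two-sided p of 0.1, so genes were tested with the spread pooled by limma.

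The pipeline was tested on simulated data over the same 14884 genes, with 200 of them changed. At a 2-fold change it recovered 82% of the changed genes for shMOF in ERα(-), 96% for shMOF in ERα(+), 90% for ERα in control arrays, 78% for ERα in shMOF arrays and 54% for the interaction. At a 1.5-fold change the shares were 46%, 34%, 46%, 46% and 8% in the same order. False calls numbered 12, 6, 15, 11 and 9. Noise was drawn independently for each gene, whereas real genes vary together, so the shares may overstate what the arrays can show. Each share rests on 50 genes in 1 draw. The 2-group comparisons share a design, so their shares do not rank their power.

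Before the data were examined, 22 gene lists were fixed, and 21 of them, with at least 3 measured members, were tested. The list of histone genes had too few measured members. The others were MOF complexes, oestrogen receptor and co-regulators, oestrogen-induced genes, endometrial epithelial genes, cell cycle and mitosis, p53 targets and cell cycle inhibitors, apoptosis, autophagy and lysosome, interferon response, NF-kB and cytokines, epithelial-mesenchymal transition, unfolded protein and ATF4 response, and hypoxia and glycolysis. Further lists were cholesterol synthesis, DNA repair, oxidative phosphorylation, endometrial cancer drivers, immediate early genes, ribosomal proteins, fibroblast and stromal cell markers, and immune and endothelial cell markers. Some genes stand in more than 1 list. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 between members, and again with the correlation estimated from the data, adjusted over the 21 lists within a comparison. Members were also counted at an adjusted p below 0.05 adjusted over the list alone. That adjustment does not cover the lists and comparisons together, so single passes may arise by chance.

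The rule for naming genes was fixed before the data were examined. It takes KAT8 and ESR1 in every sample, up to 10 genes per direction and comparison among those called (5 per direction for the interaction) whose groups did not overlap and whose mean was at or above the median of the tested genes, and up to 4 members of each list with the smallest p. XIST, Y-linked genes and symbols of unnamed loci and small RNAs were counted but not named. Alternatives fixed in advance were every named probe set, the mean of all probe sets of a gene, a filter on dim genes, quantile normalization again and arrays shifted to 1 median. So were a mean-variance trend, array quality weights, only the 2 groups compared, the replicate number as a block, the letter of the sample code as a random block, a 1.5-fold threshold, each array left out in turn, and the estimated correlation for lists. Another 3 were added after the data were seen: all probe sets of the table, the first principal component as a covariate, and 3 arrays left out. Gene positions are from GRCh38.p14. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.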

Results

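Expression was measured on 12 arrays of Ishikawa cells, an endometrial adenocarcinoma line, in 4 labelled groups of 3: control and shMOF cells, each as ERα(-) and ERα(+). MOF is the histone acetyltransferase encoded by KAT8, and ERα is the oestrogen receptor encoded by ESR1. The title of the series concerns a feedback between the 2 proteins in endometrial cancer. The design asks how lowering MOF changes transcription in each condition, how the condition changes it in control and in shMOF cells, and whether the former depends on the latter. Arrays correlated with one another at r between 0.968 and 0.989 across genes, which are not independent replicates. The median was 0.984 within groups and 0.984 between groups, and 1 of the 12 arrays had its closest partner in its own group.

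KAT8, the gene targeted by the knockdown (probe set 16818184, chromosome 16, 31117664 to 31131393, GRCh38.p14), was not detectably lower in the arrays labelled shMOF. Its log2 signal was 6.77 ± 0.10 (SD, n = 3) in control ERα(-), 6.75 ± 0.03 in shMOF ERα(-), 6.74 ± 0.12 in control ERα(+) and 6.78 ± 0.21 in shMOF ERα(+), each over 3 arrays. The log2 difference was -0.02 in ERα(-), with a 95% interval from -0.29 to 0.26, so that the interval's lower end is a fall of 18.0%. In ERα(+) it was 0.04, with an interval from -0.23 to 0.31 and a lower end at a fall of 14.8%. The KAT8 probe set lay at the 68.0th percentile of tested genes. Because the targeted gene does not follow the labels, shMOF and control below name the labels of the arrays, and every direction is between labelled arrays.

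ESR1 (probe set 17013809, chromosome 6, 151656672 to 152129619, GRCh38.p14) was not higher throughout in the arrays labelled ERα(+) either. Its values overlapped in the control arrays. In the shMOF arrays they ran against the label without overlap, from 4.27 to 4.28 in ERα(+) and from 4.34 to 4.52 in ERα(-). Its log2 signal was 4.28 ± 0.15 (SD, n = 3) in control ERα(-), 4.42 ± 0.09 in shMOF ERα(-), 4.46 ± 0.17 in control ERα(+) and 4.27 ± 0.007 in shMOF ERα(+), each over 3 arrays. The log2 difference between ERα(+) and ERα(-) was 0.18 (95% interval -0.08 to 0.45) between the arrays labelled control and -0.15 (-0.41 to 0.12) between those labelled shMOF. The probe set lay at the 27.1st percentile of tested genes, a level at which RMA can compress differences.

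**Figure D1:**
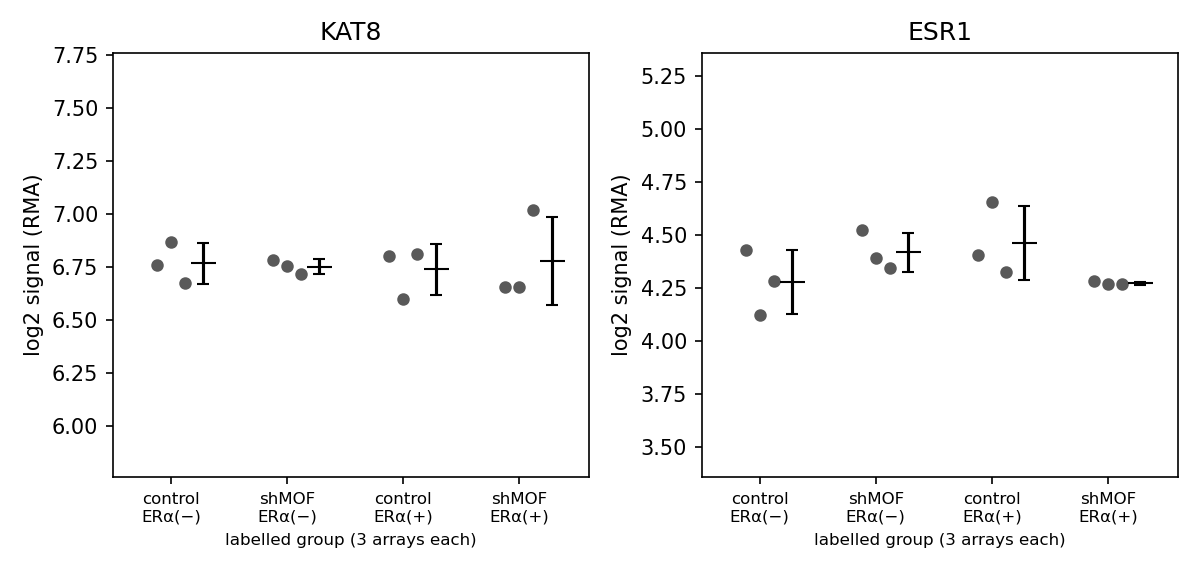
Log2 RMA signal of KAT8 and ESR1 (vertical axis) on each of the 12 arrays by labelled group (horizontal axis); points are arrays, and bars are the mean ± SD of 3 arrays. Group means of KAT8 lie between 6.74 and 6.78, and those of ESR1 between 4.27 and 4.46.

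In ERα(-), genes of the interferon response, which cells switch on after sensing virus or interferon, were lower as a list in the arrays labelled shMOF than in control arrays (median log2 fold change -0.20, 20 of 25 measured members below 0, adjusted p = 0.701 with an estimated correlation). IFIT3 differed by -0.50 ± 0.16 (SE), RSAD2 by -0.58 ± 0.21 and IFIH1, a sensor of viral RNA, by -0.64 ± 0.24, and 0 members passed adjusted over the list alone. NF-kB and cytokine genes were lower too (median -0.27, 12 of 15 below 0, adjusted p = 0.701 with an estimated correlation), with CCL2 at -0.51 ± 0.19 and CXCL2 at -0.38 ± 0.14. The unfolded protein and ATF4 response was lower (median -0.29, 13 of 16 below 0, adjusted p = 0.789 with an estimated correlation), with ATF3 at -1.22 ± 0.36. Endometrial epithelial genes (median 0.20, 13 of 16 above 0) and oxidative phosphorylation (median 0.16, 9 of 10 above 0) were higher (adjusted p = 0.789 and 0.701 with an estimated correlation). EMX2, a transcription factor of the urogenital tract, was at 0.38 ± 0.14. Of the immediate early genes, which respond first to growth signals, EGR1 was at -1.29 ± 0.28 (SE) and ATF3 at -1.22 on the log2 scale. Both passed only when adjusted over the list alone (limma adjusted p = 0.0109 and 0.0497, against 0.933 and 0.953 over all genes). The list as a whole was not called (median -0.08, camera adjusted p = 0.0823), but it was called downward without shMOF ERα(-) replicate 1 (-0.20, adjusted p = 0.00839), shMOF ERα(-) replicate 3 (-0.09, 0.0162) or control ERα(-) replicate 3 (-0.17, 0.00277). So it was with the code letter as a block (-0.16, 0.0179) or the first principal component as a covariate (-0.19, 2.15e-04). It was called in only these 5 of 23 alternatives, whose medians ran from -0.20 to 0.08. The highest camera adjusted p was 0.964, without shMOF ERα(-) replicate 2.

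These 5 lists were called by camera with the preset correlation (adjusted p = 4.58e-05 for interferon, 6.73e-04 for NF-kB, 0.0129 for the unfolded protein response, 0.0141 for endometrial epithelial genes and 0.0129 for oxidative phosphorylation), and 0 of the 21 were called with an estimated correlation (lowest adjusted p = 0.701). Oestrogen-induced genes had a median of 0.03 but a mean and a test direction below 0 (camera adjusted p = 0.95). Of them, the classical target GREB1 was at -0.31 ± 0.13 and TSKU at 0.52 ± 0.21. The MOF complexes had a median of 0.04, again with a mean and a test direction below 0 (adjusted p = 0.95). Medians of the other lists were -0.08 for oestrogen receptor and co-regulators, 0.05 for cell cycle, -0.02 for p53 targets, -0.09 for apoptosis, and -0.07 for autophagy, none of them called. Medians were -0.06 for epithelial-mesenchymal transition, -0.31 for hypoxia and glycolysis, 0.006 for cholesterol synthesis (with a mean below 0), -0.05 for DNA repair, 0.02 for endometrial cancer drivers (with a mean below 0) and 0.06 for ribosomal proteins, none of them called. Cell cycle genes were called upward without control ERα(-) replicate 2 (0.08, adjusted p = 0.0129) or 3 (0.09, 0.0185) and with the code letter as a block (0.06, 0.037). Ribosomal proteins were called upward without control ERα(-) replicate 2 (0.08, 0.0476) or shMOF ERα(-) replicate 2 (0.09, 0.0291), with the mean of all probe sets of a gene (0.07, 0.044) and with every named probe set (0.06, 0.0348). These were 4 of 23 alternatives. The lowest median was -0.006, and the highest camera adjusted p was 0.617, without shMOF ERα(-) replicate 1. Markers of fibroblasts and stroma (median 0.04) and of immune and endothelial cells (0.09) were not called. Over all genes limma called 0 of 14884 (smallest adjusted p = 0.265), with 711 at an unadjusted p below 0.05 where 744.2 are expected by chance. Groups did not overlap for 8.76% of genes, against 10% by chance. Without control ERα(-) replicate 1 the median of the unfolded protein response turned to 0.11, and hypoxia and glycolysis turned to 0.19 and was called upward (adjusted p = 2.94e-05), while it was called downward without control ERα(-) replicate 2 or 3 or shMOF ERα(-) replicate 3 (-0.55, -0.54 and -0.35). The calls of NF-kB (median -0.10, adjusted p = 0.109), endometrial epithelial genes (0.13, 0.115) and oxidative phosphorylation (0.12, 0.109) ended as well. On control ERα(-) replicate 1 the mean of the unfolded protein list was 8.60, against at most 7.73 on the other arrays, so its fall depends on that array. Hypoxia and glycolysis was also called downward with the filter on dim genes (-0.31), the code letter as a block (-0.35) and the first principal component as a covariate (-0.41). Without shMOF ERα(-) replicate 2 limma called 5 genes, 1671 had an unadjusted p below 0.05, and the calls of NF-kB (median -0.13, adjusted p = 0.178) and the unfolded protein response (-0.19, 0.306) ended. Without shMOF ERα(-) replicate 1 the calls of endometrial epithelial genes (median 0.10, adjusted p = 0.211) and oxidative phosphorylation (0.09, 0.0601) ended, and without replicate 3 that of endometrial epithelial genes (0.13, 0.0503). In the latter case 434 genes had an unadjusted p below 0.05. Without 3 arrays, chosen after seeing the data, the calls of all lists but interferon ended. With the first principal component as a covariate, also chosen after, those of endometrial epithelial genes and oxidative phosphorylation ended (both medians 0.073, adjusted p = 0.412 and 0.0851). The filter on dim genes ended those of endometrial epithelial genes (at a like median of 0.20, adjusted p = 0.059) and NF-kB (median -0.11, 0.13), and array quality weights those of NF-kB (at a like median of -0.27, 0.362) and the unfolded protein response (median 0.00077, 0.737). With every named probe set the NF-kB median was -0.15. The interferon median was -0.13 without control ERα(-) replicate 1 or shMOF ERα(-) replicate 3, and without control ERα(-) replicate 3 those of NF-kB and the unfolded protein response were -0.40 and -0.54.

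In ERα(+), interferon response genes were higher in the arrays labelled shMOF than in control arrays (median log2 fold change 0.53, 22 of 25 above 0, adjusted p = 0.473 with an estimated correlation), and 13 rose when adjusted over the list alone. IFI44L rose by 1.66 ± 0.26 (SE), IFIT1, which binds foreign RNA, by 1.07 ± 0.19, IFIT3 by 0.92 ± 0.16 and SAMD9 by 1.62 ± 0.32 on the log2 scale. CXCL10, an interferon-inducible chemokine in the NF-kB list, rose by 1.02 ± 0.19, while that list had a median of -0.28 and was not called (adjusted p = 0.451), though it was called downward with every named probe set (-0.36, 0.00647). DNA repair genes were higher as a list (median 0.25, 14 of 19 above 0, adjusted p = 0.801 with an estimated correlation), with RAD50 at 0.61 ± 0.24 and NBN at 0.54 ± 0.23, which act together at broken DNA ends. Ribosomal proteins (median -0.15, 25 of 27 below 0) and immediate early genes (median -0.24, 19 of 21 below 0) were lower (both adjusted p = 0.801 with an estimated correlation). RPS16 was at -0.39 ± 0.15 and FOSL1 at -0.89 ± 0.24. RRM2B, a p53-induced ribonucleotide reductase subunit, was at 0.88 ± 0.24 and passed only when adjusted over the list alone (limma adjusted p = 0.0409).

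Camera with the preset correlation called these 4 lists (adjusted p = 2.78e-10 for interferon and 0.0109 for each of the others), and with an estimated correlation 0 (lowest adjusted p = 0.473). Oestrogen-induced genes had a median of -0.10 (camera adjusted p = 0.245), with TFF1 at -0.39 ± 0.17 and IGFBP4 at -0.37 ± 0.13. Their median ran from -0.18 to 0.03 over 23 alternatives, of which 0 called the list. The MOF complexes had a median of -0.03 (adjusted p = 0.972), with OGT at 0.37 ± 0.12. Over all genes limma called 0 (smallest adjusted p = 0.0988), with 2787 at an unadjusted p below 0.05 (1520 higher and 1267 lower) against 744.2 expected, and 26.2% of genes had groups that did not overlap against 10% by chance. The count of 2787 fell to 1182 without control ERα(+) replicate 3 and to 1048 without shMOF ERα(+) replicate 2, the arrays at the ends of the first principal component, which held 36.8% of the variance. With that component as a covariate, an alternative chosen after seeing the data, it was 588, and the medians of DNA repair and immediate early genes turned to -0.048 and 0.11 and the call of ribosomal proteins ended (-0.027). The component lay above 0 on all control ERα(+) arrays and below 0 on all shMOF ERα(+) arrays. As a covariate it therefore takes out part of this comparison. With every named probe set the DNA repair call ended (median 0.13, adjusted p = 0.219), and without 3 arrays the calls of all lists but interferon did. Array quality weights ended the call of immediate early genes (median -0.13, adjusted p = 0.195) and took the DNA repair median to 0.14, and the filter on dim genes ended the DNA repair call at an unchanged median of 0.25 (0.0671). The calls of DNA repair and immediate early genes ended without control ERα(+) replicate 3 (medians 0.13 and -0.15, both adjusted p = 0.16) and without shMOF ERα(+) replicate 2 (0.18 and -0.14, 0.0703 and 0.0856). That of ribosomal proteins ended without shMOF ERα(+) replicate 2 (median -0.14, adjusted p = 0.0703) and without control ERα(+) replicate 1 (-0.13, 0.0774), and the median of immediate early genes was -0.35 without control ERα(+) replicate 2. Limma called 30 genes without shMOF ERα(-) replicate 2 and 1 without control ERα(+) replicate 3.

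**Figure D2:**
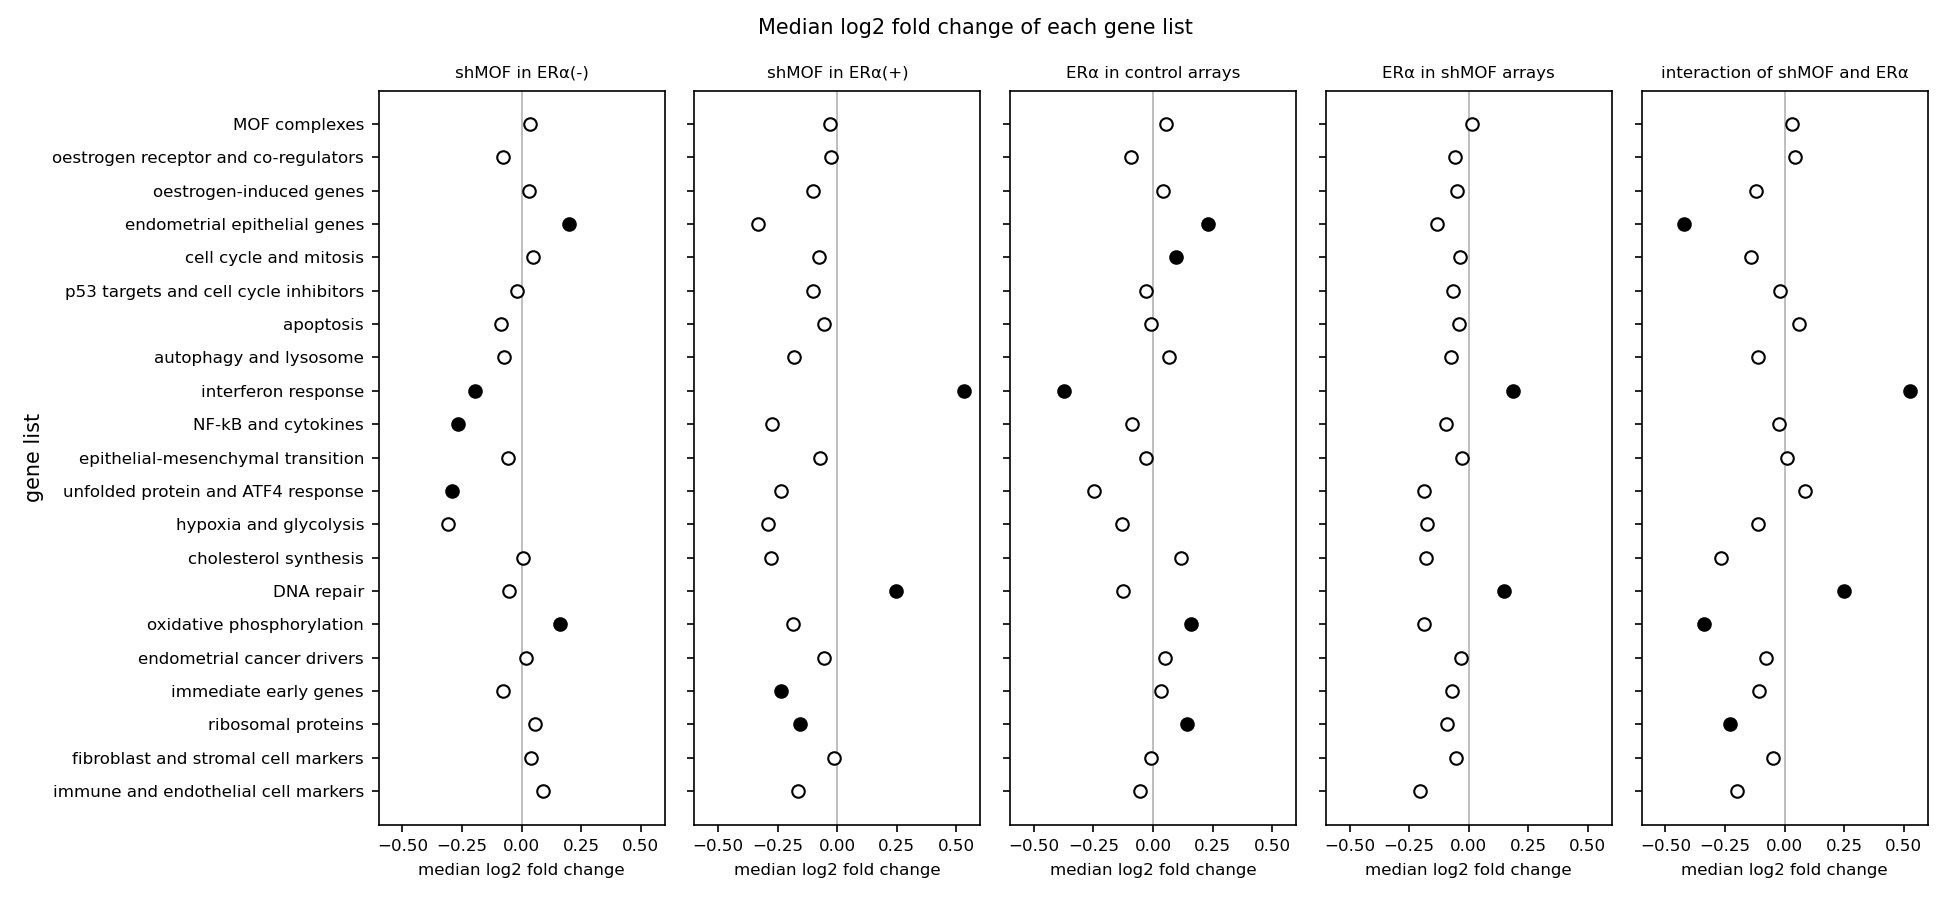
Median log2 fold change (horizontal axis) of each of the 21 gene lists (vertical axis) in the 5 comparisons; filled points are lists called by camera with the preset correlation at an adjusted p below 0.05. The interferon response list lies at -0.20, 0.53, -0.37, 0.19 and 0.53 from left to right, and none of the lists was called with an estimated correlation.

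Between the control arrays labelled ERα(+) and ERα(-), interferon response genes were lower in ERα(+) (median log2 fold change -0.37, 22 of 25 below 0, adjusted p = 0.713 with an estimated correlation), and 13 fell when adjusted over the list alone. IFI44L fell by 1.23 ± 0.26 (SE), IFIH1 by 1.04 ± 0.24, RIGI, another sensor of viral RNA, by 0.94 ± 0.23 and IFIT3 by 0.78 ± 0.16 on the log2 scale. Endometrial epithelial genes were higher (median 0.23, 14 of 16 above 0, adjusted p = 0.864 with an estimated correlation), and EMX2 rose by 0.51 ± 0.14 (limma adjusted p = 0.0369 adjusted over the list alone). FOXA2, a factor of endometrial glands, was at 0.43 ± 0.16 and LGR5 at -1.31 ± 0.51. Ribosomal proteins (median 0.14, 25 of 27 above 0), oxidative phosphorylation (0.16, 9 of 10) and cell cycle genes (0.10, 30 of 42) were higher (each adjusted p = 0.864 with an estimated correlation). The mitotic kinase PLK1 was at 0.47 ± 0.16. The tight junction gene OCLN was at -0.59 ± 0.15 and the glycolytic PGAM1 at 0.52 ± 0.12, and both passed only when adjusted over their lists alone (limma adjusted p = 0.0389 and 0.0158).

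Camera called these 5 lists with the preset correlation (adjusted p = 1.84e-08 for interferon, 0.00565 for endometrial epithelial genes, 0.0106 for ribosomal proteins, 0.0197 for oxidative phosphorylation and 0.0272 for cell cycle) and 0 with an estimated one (lowest adjusted p = 0.713). Oestrogen-induced genes, the list named for the receptor's activity, had a median of 0.04 (camera adjusted p = 0.682), with 19 of 35 members above 0. Among them TSKU was at 0.71 ± 0.21. Of the classical targets, chosen after their values were seen, GREB1 was at -0.28 ± 0.13 and PGR, the progesterone receptor, at -0.30 ± 0.17. MYC, of the same list, went the other way at 0.15 ± 0.14. PGR was dim, with means of 3.47 in control ERα(-) and 3.17 in control ERα(+), against a median level of 5.66 for tested genes. Over all genes limma called 0 (smallest adjusted p = 0.319), with 1894 at an unadjusted p below 0.05 against 744.2 expected, and with only these 6 arrays in the fit it called 9. The count of 1894 fell to 1254 without control ERα(-) replicate 1 and to 1116 without control ERα(+) replicate 3, and hypoxia and glycolysis turned from a median of -0.13 to 0.27 without the former and was called upward (adjusted p = 3.44e-05), while it was called downward without control ERα(-) replicate 2 or 3 (-0.44 and -0.46). The cell cycle call ended without control ERα(-) replicate 1 (adjusted p = 0.327) and control ERα(+) replicates 1 (0.0893) and 2 (0.14), at medians of 0.12, 0.10 and 0.12 against 0.10 with all arrays. That of oxidative phosphorylation ended without control ERα(-) replicate 1 (median 0.19, adjusted p = 0.0773) and control ERα(+) replicate 1 (0.19, 0.076), and that of ribosomal proteins without the latter (0.10, 0.0893). With the filter on dim genes the calls of all lists but interferon ended at about the same medians (0.21 for endometrial epithelial genes, 0.10 for cell cycle, 0.17 for oxidative phosphorylation and 0.14 for ribosomal proteins). They ended without 3 arrays (0.14, 0.08, 0.14 and 0.10 in the same order), and those of endometrial epithelial genes, oxidative phosphorylation and ribosomal proteins with the first principal component as a covariate (medians 0.031, 0.022 and 0.0099). That component parted these 2 groups by sign, so as a covariate it takes out part of this comparison. Array quality weights ended the cell cycle call at a like median of 0.10 (adjusted p = 0.0691). The median of endometrial epithelial genes was 0.11 without control ERα(+) replicate 3, and that of cell cycle genes 0.15 without control ERα(-) replicate 2. Limma called 4 genes without shMOF ERα(-) replicate 2.

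Between the shMOF arrays labelled ERα(+) and ERα(-), interferon response genes were higher in ERα(+) (median log2 fold change 0.19, 22 of 25 above 0, adjusted p = 0.639 with an estimated correlation), and 10 rose when adjusted over the list alone. IFI44L rose by 1.10 ± 0.26 (SE), DDX60 by 0.97 ± 0.26, IFIT3 by 0.64 ± 0.16 and HERC6 by 0.49 ± 0.13 on the log2 scale, and CXCL10 by 0.73 ± 0.19. DNA repair genes were higher as a list (median 0.15, 15 of 19 above 0, adjusted p = 0.931 with an estimated correlation), with TP53BP1 at 0.28 ± 0.13. Oestrogen-induced genes had a median of -0.05 (camera adjusted p = 0.617), with CXCL12 at -0.33 ± 0.12. CSF1R and NKG7, which mark macrophages and cytotoxic lymphocytes, differed by -0.42 ± 0.14 and -0.37 ± 0.12 (both limma adjusted p = 0.0416 adjusted over the list alone), while their list had a median of -0.20 and was not called. That list was dim, with a mean signal of 4.57 in shMOF ERα(-) and 4.40 in shMOF ERα(+), against a median level of 5.66 for tested genes. These values do not show that such cells were present.

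Camera called these 2 lists with the preset correlation (adjusted p = 6.31e-09 and 0.0416) and 0 with an estimated one (lowest adjusted p = 0.639). Over all genes limma called 0 (smallest adjusted p = 0.746), with 793 at an unadjusted p below 0.05 against 744.2 expected, and groups did not overlap for 9.51% of genes against 10% by chance. Without shMOF ERα(-) replicate 2 there were 2587 at an unadjusted p below 0.05 and 11 called, and without shMOF ERα(-) replicates 1 and 3 and shMOF ERα(+) replicate 2 there were 437, 491 and 436. The DNA repair call ended without shMOF ERα(-) replicate 1 (median 0.074, adjusted p = 0.384) and shMOF ERα(+) replicates 2 (0.072, 0.308) and 3 (0.15, 0.056), and with the first principal component as a covariate its median turned to -0.033. It also ended without 3 arrays (0.072), with the filter on dim genes at an unchanged median (0.15), and with quantile normalization again (0.12), array quality weights (0.14) or the code letter as a block (0.13). Its median was 0.031 with every named probe set. The interferon median was 0.30 without shMOF ERα(+) replicate 1, 0.11 without replicate 3, 0.32 with the first principal component as a covariate and 0.39 with array quality weights.

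The interaction asks whether the difference between arrays labelled shMOF and control depends on the condition. Interferon response genes had the largest median of the 21 lists (0.53 on the log2 scale, 23 of 25 above 0, adjusted p = 0.443 with an estimated correlation), and 13 passed upward when adjusted over the list alone. IFI44L had an interaction of 2.33 ± 0.37 (SE), IFIH1 of 1.83 ± 0.34, IFIT3 of 1.42 ± 0.22, HERC5 of 1.28 ± 0.26 and CXCL10 of 1.47 ± 0.27. DNA repair genes were above 0 as a list (median 0.25), and ribosomal proteins (-0.23), oxidative phosphorylation (-0.34) and endometrial epithelial genes (-0.42) below (each adjusted p = 0.959 with an estimated correlation). Within the latter, EMX2 at -0.64 ± 0.19 and FOXA2 at -0.67 ± 0.22 went against LGR5, a marker of epithelial stem cells, at 2.32 ± 0.72 (limma adjusted p = 0.0483 for each, adjusted over the list alone). MED1, a co-activator of nuclear receptors, had an interaction of 0.67 ± 0.18 and ARID5B, mutated in endometrial cancer, of 1.34 ± 0.37 (adjusted p = 0.0454 and 0.0413, adjusted over their lists alone).

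Camera with the preset correlation called these 5 lists (adjusted p = 1.37e-10 for interferon, 0.00968 for ribosomal proteins, 0.0123 for endometrial epithelial genes, 0.0174 for oxidative phosphorylation and 0.0356 for DNA repair), and with an estimated correlation 0 (lowest adjusted p = 0.443). Oestrogen-induced genes had a median of -0.12 (camera adjusted p = 0.581). Over all genes limma called 0, with 2685 at an unadjusted p below 0.05 (smallest adjusted p = 0.0696). Without shMOF ERα(-) replicate 2 limma called 570 genes and 4036 had an unadjusted p below 0.05, and with array quality weights it called 3258. The unadjusted count was 1555 without shMOF ERα(-) replicate 1, 1719 without control ERα(+) replicate 3 (1 called) and 1494 without shMOF ERα(+) replicate 2. For this test 11 genes were called without shMOF ERα(+) replicate 1. The DNA repair call ended without control ERα(-) replicates 2 (adjusted p = 0.0746) and 3 (0.086), shMOF ERα(-) replicate 1 (0.0986), control ERα(+) replicate 3 (0.179) and shMOF ERα(+) replicate 2 (0.101), at medians of 0.27, 0.23, 0.16, 0.22 and 0.20. With the first principal component as a covariate the medians of DNA repair and endometrial epithelial genes turned to -0.063 and 0.11, and the calls of oxidative phosphorylation (-0.071) and ribosomal proteins (-0.022) ended. That component largely follows the interaction, so as a covariate it takes out part of the interaction. With every named probe set the DNA repair median was 0.043 and the call ended (adjusted p = 0.744), and without 3 arrays the calls of all lists but interferon ended. The DNA repair call also ended with the filter on dim genes (adjusted p = 0.0765), quantile normalization again (0.0603), array quality weights (0.0644) and the code letter as a block (0.0782), at medians of 0.25, 0.22, 0.25 and 0.22 against 0.25 in the analysis above. The filter ended those of endometrial epithelial genes and oxidative phosphorylation (both 0.0627) at like medians of -0.41 and -0.34. The median of endometrial epithelial genes was -0.27 without shMOF ERα(+) replicate 2, and hypoxia and glycolysis went from -0.11 to -0.52 and was called without control ERα(-) replicate 1 (adjusted p = 5.97e-05). SOBP, singled out after its values were seen, had an interaction of 1.21 ± 0.19 (adjusted p = 0.0696).

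**Figure D3:**
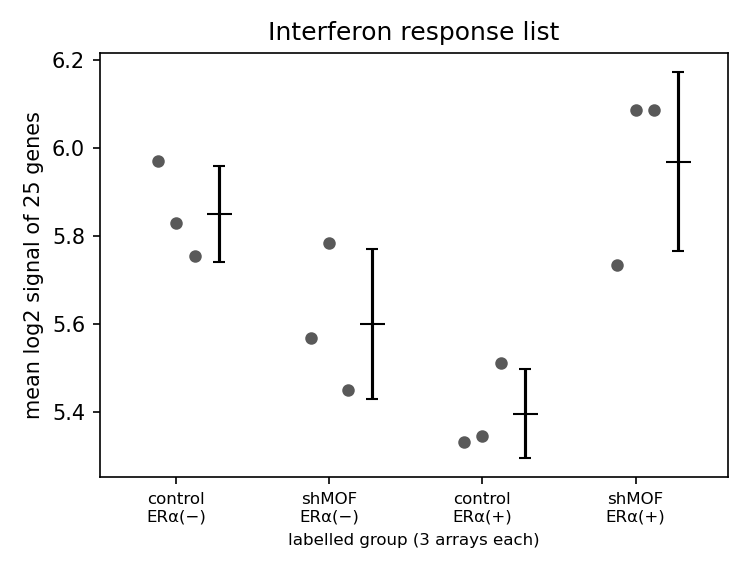
Mean log2 signal of the 25 measured interferon response genes (vertical axis) on each array by labelled group (horizontal axis); points are arrays, and bars are the mean ± SD of 3 arrays. Means are 5.85 in control ERα(-), 5.60 in shMOF ERα(-), 5.40 in control ERα(+) and 5.97 in shMOF ERα(+).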

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

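The tests of explanations below, splits included, were chosen only after the results were seen. A test of the difference between conditions by camera with a preset correlation singled out 5 gene lists whose shift between arrays labelled shMOF and control was not the same in ERα(+) as in ERα(-). With an estimated correlation 0 of them were called (lowest adjusted p = 0.443). The median interaction was 0.53 for interferon response, 0.25 for DNA repair, -0.42 for endometrial epithelial genes, -0.34 for oxidative phosphorylation and -0.23 for ribosomal proteins. The 4 lists other than interferon response lost their calls with the first principal component as a covariate, at medians of -0.063 for DNA repair, 0.11 for endometrial epithelial genes, -0.071 for oxidative phosphorylation and -0.022 for ribosomal proteins. That component lay below 0 on all control ERα(-) and shMOF ERα(+) arrays. It lay above 0 on all others but shMOF ERα(-) replicate 2, so it largely follows the interaction itself. As a covariate it takes out part of the interaction, so the lost calls do not tell an artefact from a difference.

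The interaction was set against 100 splits, the real one included, drawn from the 200 that exchange the labels shMOF and control within conditions. For the interferon list, 5 of these 100 gave a camera p as small as the real 6.5e-12, and the smallest other was 9.18e-18, so chance cannot be excluded. With the main axis of variation between arrays, computed without the list, as a covariate, the median interaction was 0.66, against 0.53 without. The list stayed called with the preset correlation (camera adjusted p = 1.75e-14), though without the covariate it was not called with an estimated correlation (adjusted p = 0.443). This argues only against a linear effect of that axis as the whole cause. Because the axis largely follows the interaction, 0.66 is no better an estimate. The first principal component over all genes lay below 0 on all arrays of code sets 1 and 3, given below. On the other arrays it lay above 0, except on shMOF ERα(+) replicate 1, so the covariate does not weigh against that split. Mislabelled samples stay open: 119 of the 15400 partitions of the 12 arrays into 4 sets of 3 hold as large a share of the list mean's variance as sets of consecutive sample codes do (77.1%), and 136 as large a share as the labelled groups (76.3%), so by this share the groupings cannot be told apart. The list mean was 5.75 to 6.09 on the arrays of code sets 1 and 3, given below, and 5.33 to 5.73 in sets 2 and 4. By the labels, shMOF ERα(-) replicate 2 (5.78) lay above control ERα(-) replicate 3 (5.75). The code split was noticed in these same arrays, so this does not decide for it. An effect of MOF on interferon genes that depends on the condition may also account for the interaction of the list, and the flat KAT8 signal leaves that untested.

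The counts at an unadjusted p below 0.05 were set against other splits of the same 6 arrays, of which there are 10, too few for a share below 0.05. For shMOF in ERα(-), 4 of them, the real one included, gave at least the real 711, and the highest other was 2064. For shMOF in ERα(+) the real 2787 was 1 of 10, with 2156 as the highest other. For ERα in control arrays the real 1894 was 1 of 10, with 1439 as the highest other. For ERα in shMOF arrays, 3 gave at least 793, with 2875 as the highest other. For the interaction, 3 of the 100 splits drawn from 200 gave at least the real 2685, with 3500 as the highest other. This share is below 0.05, but the test was chosen after the results and was not adjusted for the other counts tested. It also rests on a draw of 100 from the 200 splits, so chance is not excluded for the interaction count. The count was 758 with the first principal component as a covariate and 940 without 3 arrays, both chosen after seeing the data. It was 1494 without shMOF ERα(+) replicate 2 and 4036 without shMOF ERα(-) replicate 2, where 744.2 are expected by chance, so it depends on which arrays are used.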

How the results depend on the processing

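The alternatives on the first principal component, on 3 arrays left out and on all probe sets, and the splits with array weights, were chosen only after the results were seen. With 0 genes called by limma in each of the 5 comparisons, an alternative can only add calls, and the cause was not tested where it did. Counts are given in the order shMOF in ERα(-), shMOF in ERα(+), ERα in control arrays, ERα in shMOF arrays and the interaction. Array quality weights called 645, 1629, 217, 1918 and 3258, with 3813, 4762, 3687, 4912 and 5734 at an unadjusted p below 0.05. The weights ran from 0.359 to 8.86. The highest was that of shMOF ERα(-) replicate 3, against 0.591 for replicate 1 and 0.359 for replicate 2 of that group. Control ERα(+) replicate 1, at 3.70, had by far the highest weight of its group. The weighted means of these groups thus rest mainly on 1 array each. Each of the 5 comparisons uses at least 1 of these groups, so the calls with weights lean on single arrays. Of 100 splits of the labels drawn from 200, 4, with weights estimated again, called at least 3258 for the interaction (highest other 3863). As the test was chosen after the results and only a part of the splits was drawn, chance is not excluded. Of the other splits 34 called at least 1 gene, with a median of 0 calls. Only the 2 groups compared gave 9 for ERα in control arrays. The code letter as a random block (consensus correlation -0.147) gave 5 for the interaction. The replicate block gave 2 for the interaction and changed none of the other 4 counts of calls. The numbers do not pair the arrays throughout: 5 of 18 same-numbered pairs deviated together at r over 0.1, and 3 arrays correlated best with their own number. Replicate 2 of shMOF ERα(-), control ERα(+) and shMOF ERα(+) did deviate together, at r from 0.24 to 0.45. Control ERα(-) replicate 2 did not join them (r from -0.18 to 0.07), and a pair of unlike numbers reached 0.37. Why those arrays deviated together was not tested. With each array left out in turn, calls ranged from 0 to 5, 0 to 30, 0 to 4, 0 to 11 and 0 to 570. Unadjusted counts ranged from 434 to 1671, 1048 to 3473, 1116 to 2463, 436 to 2587 and 1494 to 4036. The highest number of calls in each came without shMOF ERα(-) replicate 2, 1 of the arrays on which the interaction departs from the split of code sets given below. The filter on dim genes, which tests fewer genes, gave unadjusted counts of 292 for shMOF in ERα(-) and 321 for ERα in shMOF arrays, and the 1.5-fold threshold, stricter by construction, 107, 536, 329, 97 and 1542.

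The first principal component as a covariate gave unadjusted counts of 919, 588, 1114, 515 and 758, so that the first rose from 711 and the others fell. Arrays labelled control ERα(-) and shMOF ERα(+) all lay below 0 on this component, and control ERα(+) arrays all above. As a covariate it takes out part of the shMOF difference in ERα(+), of the ERα difference in control arrays and of the interaction. Without the 3 arrays furthest out on the first 2 components (control ERα(-) replicate 1, control ERα(+) replicate 3 and shMOF ERα(+) replicate 2) the unadjusted counts were 552, 685, 800, 497 and 940, with 1 call for shMOF in ERα(+) and 1 for the interaction. Testing all probe sets changed no count of calls. Of 21 list calls with the preset correlation, 21 were lost with an estimated one. The interferon list was called in 23 of 23 other alternatives in each comparison, with medians from -0.28 to -0.13, 0.39 to 0.57, -0.52 to -0.27, 0.11 to 0.39 and 0.46 to 0.77. The other calls held in 11 (DNA repair, interaction) to 21 (ribosomal proteins, interaction) of 23. The first component as a covariate ended 13 of the 21 calls, 3 arrays left out 16, the filter on dim genes 11 and array quality weights 6, and alternatives added 64 calls in 28 lists and comparisons. Of 105 medians, 78 changed sign in at least 1 alternative. The 14 turns in the test's direction in which the list was called before or after were the following. With the first component as a covariate, DNA repair went to -0.048 for shMOF in ERα(+), -0.033 for ERα in shMOF arrays and -0.063 for the interaction. Immediate early genes went to 0.11 for shMOF in ERα(+), -0.21 for ERα in control arrays and 0.26 for the interaction, and endometrial epithelial genes to 0.11 for the interaction. Without control ERα(-) replicate 1, the unfolded protein response went to 0.11 for shMOF in ERα(-) and -0.34 for the interaction, and hypoxia and glycolysis to 0.19 for shMOF in ERα(-) and 0.27 for ERα in control arrays. With each array left out in turn, these ranged from -0.54 to 0.11, -0.34 to 0.37, -0.55 to 0.19 and -0.46 to 0.27. Without the 3 arrays these were 0.11, 0.19 and 0.20 for the unfolded protein response and hypoxia in shMOF in ERα(-) and hypoxia in control arrays. Control ERα(-) replicate 1 had list means of 8.60 for the unfolded protein response and 8.33 for hypoxia and glycolysis. The other arrays had at most 7.73 and 7.25, so the turns without control ERα(-) replicate 1 rest on that array. Why it stood apart was not tested. Background was not measured here, so what signal over background limits for ESR1, at the 27.1st percentile of levels, is open.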

Other observations

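All tests in this part were chosen only after the data were seen. Fold changes between arrays labelled shMOF and control ran against each other in the 2 conditions, with r = -0.387 (rho = -0.370) across the 14884 genes. Those between ERα(+) and ERα(-) ran against each other in control and in shMOF arrays, with r = -0.488 (rho = -0.460). Each pair shares no array, and genes are not independent replicates. Of the 37519 unnamed probe sets, limma called 0 in each comparison, with 1792, 4204, 3562, 1805 and 3876 at an unadjusted p below 0.05 where 1876 are expected by chance (shMOF in ERα(-), shMOF in ERα(+), ERα in control arrays, ERα in shMOF arrays and the interaction).

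A grouping of the arrays by sample code was noticed in the data. Each sample carries a code of a letter and a number, and the labels give groups to the codes in alphabetical order (A1, A2 and B1 are control ERα(-), for example). Taken by number and then letter, the codes form 4 consecutive sets of 3, to which no condition is assigned here. Set 1 is A1, B1 and C1, set 2 is D1, E1 and F1, set 3 is G1, H1 and A2, and set 4 is B2, C2 and D2. An F test in limma called 150 genes between these sets (smallest adjusted p = 5.12e-07) and 0 between the labelled groups, with 2575 and 1330 at an unadjusted p below 0.05. Between sets 1 and 3, and between sets 2 and 4, limma called 0 genes. Unadjusted counts there were 670 and 773, where 744.2 are expected by chance. The calls thus reflect mainly a split of sets 1 and 3 against sets 2 and 4, and do not show 4 separate groups. Of 98 random partitions, 2 called at least 150, the median was 0 and the highest 454. IGF2BP1, an RNA-binding protein of fetal and tumour cells singled out after its values were seen, had log2 signals from 7.14 to 7.22 in set 1 and 7.71 to 8.05 in set 3. They were 5.23 to 5.62 in set 2 and 5.34 to 5.57 in set 4. NEXMIF, CAPN6 and LRCH2, chosen the same way, were higher in sets 1 and 3, and FN1, a matrix protein, in sets 2 and 4. Sets 1 and 3 hold all control ERα(-) arrays, shMOF ERα(+) replicates 2 and 3 and shMOF ERα(-) replicate 2. The interaction sets control ERα(-) and shMOF ERα(+) against the other groups. It thus follows this split on all arrays but shMOF ERα(-) replicate 2 and shMOF ERα(+) replicate 1. The interaction results and the opposed fold changes above are therefore not observations apart from this split.

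A candidate explanation is that groups were given to the wrong samples. Because the order was noticed in these same arrays, its calls and its rank among partitions restate that observation and do not weigh for wrong labels, which stay open. The code sets hold 40.9% of the variance over genes, a share that 186 of the 15400 partitions reach, and the labelled groups 34.3%, which 1916 reach, so chance is not excluded for the labels. With each gene scaled to the same variance, the most variable genes alone or the genes at or above the median level alone, 379, 27 and 347 partitions reach the share of the code sets, and 2053, 1787 and 2326 that of the labelled groups. A smooth trend along the codes is argued against: sets 1 and 3 differ by 670 genes at an unadjusted p below 0.05 and sets 2 and 4 by 773. Sets next to each other differ by 2585, 2886 and 2260. Sets 1 and 4, at the ends, differ by 2453 (160 called), as a trend would have it, but a trend would also part sets 1 and 3 and sets 2 and 4 by more than their neighbours. Processing in sets of 3 was not tested and stays open, as does a biological difference between the sets.

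The highest and lowest KAT8 signals of all 12 arrays differ by 0.42 on the log2 scale, less than any 2-fold change. Wrong labels therefore do not account for the flat KAT8 signal if the knockdown lowered its transcript 2-fold or more and the probe set reports such a fall in full. Whether it does was not tested. For ESR1 the range is 0.53, and its level at the 27.1st percentile keeps the question open. A fall of the transcript by less than 2-fold or none, a knockdown seen only in the protein, or a probe set that misses or understates the change may account for KAT8. None of these was tested.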
